A study of Solanum lycopersicum with 48 samples.

How the data were processed

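RNA was measured by sequencing in roots and leaves of 2 tomato cultivars, Guizhen No.1 and Guozhen No.1, grown hydroponically in Hoagland solution in a growth chamber at 9 mM nitrogen (labelled as the control, here normal nitrogen) or 1 mM nitrogen (low nitrogen), and collected at day 1 and day 7. The labels do not say from which event the days were counted or which cultivar is the more tolerant. Nor do they say whether the 3 replicates of a group are separate plants, so the limma p-values of single genes measure the spread between samples. Per the labels, RNA was extracted with a Tiangen kit and libraries were made with the NEBNext Ultra kit. Groups of all 48 libraries were taken from the sample titles, giving 16 groups of 3.

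The values are FPKM (fragments per kilobase of gene model, scaled to the mapped fragments of a library), as deposited by the authors in 1 table for all libraries. Per the submitters' processing notes, HISAT2 and StringTie were used, but their versions, the genome build and the annotation release were not given in the sources used here. The table held 29898 genes, none of them 0 in all libraries. Column sums lay between 577123 and 689680, so that the values are neither counts nor TPM, and 16983 to 18640 genes per library reached 1 FPKM. The number of reads per library was not given. A relative depth was therefore estimated from the commonest ratio between 2 libraries of values below 0.15 FPKM, where 1 fragment decides the value, and ran from 0.75 to 2.11 times that of the median library, the deepest being Guozhen root at day 7, normal nitrogen, replicate 2. Without counts the sampling error of low values could not be computed, and an exact 0 can be a failed estimate. In root, 53 of 10532 genes with a mean of at least 10 FPKM had a 0 in some library, and in leaf 139 of 9733.

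Each organ was analysed on its own with its 24 libraries. Values were transformed to log2(FPKM + 1), with a pseudocount of 1, and genes with at least 1 FPKM in at least 3 of the 24 libraries were kept. Linear models with 1 mean per group were fitted with limma 3.58.1 in R 4.3.3, with a trend of variance on mean, so that the 8 groups of an organ share their estimate of spread. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p below 0.05 were called. Standard errors are those of limma. With 3 against 3 libraries an exact permutation test cannot reach a p below 0.1, so that no such test was used for single genes. The comparisons were low against normal nitrogen in each cultivar, organ and day, the difference of that response between the cultivars, and the cultivars at normal nitrogen. The difference of the response between days, and the overlap of root with leaf responses, were added after the data were seen.

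Named genes were chosen by a fixed rule: per comparison, up to 2 with the largest rise and 2 with the largest fall among called genes whose higher group mean reached 5 FPKM and whose libraries did not overlap between the groups (for the response differences, without the last condition), and all called genes where 5 or fewer were called. Newly assembled genes were tested but not named. The gene table supplied for tomato (41476 entries) shared no identifier with the deposited table, so that lists chosen by gene name were not used. In their place, 13 preset locus numbers of nitrogen transport and assimilation were read, of which 12 were in the table and 11 passed the filter in each organ. The class printed with a locus was preset for that locus number. It was not read from the data and could not be checked against a map of locus numbers to gene names. For 7 of the 12 a matching symbol lies on the same chromosome in the supplied table, and the rest had no symbol to compare. The list was tested with camera in limma with a preset correlation of 0.01, and again with the correlation between the loci estimated from the data. Overlaps of called genes were tested with the hypergeometric test among genes tested in both comparisons. That test treats genes as independent draws, so that its p-values do not measure the spread between samples. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

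The fit was tested on simulated data that kept each gene's normal nitrogen means and its spread between replicates in the real libraries and changed 200 genes of at least 10 FPKM. In Guizhen roots of day 7, 66% of changes of 1 and 89% of changes of 2 on the log2 scale were found, with 10 false among 165 calls over 20165 genes. In Guizhen leaves of day 7, the shares were 71% and 92%, with 11 false among 174 calls over 19489 genes. The simulated spread was the same in all groups and independent between genes, so that the shared spread assumed by the fit held by design. Libraries that stand apart from their group were not simulated, so that these shares of false calls need not hold for the real counts.

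Each comparison was repeated with a pseudocount of 0.1, with no filter on low values, with median-of-ratios scaling of the libraries, with only the libraries compared, with the replicate number as a block, with robust variance estimation, and leaving out each library in turn. In the last, a group left with 2 libraries is assumed to vary like the others. Overlaps were repeated at an adjusted p below 0.01. Labels were checked by sets of genes preferred in leaf, which put every library with its organ. They were also checked by genes differing over 8-fold between the cultivars in the other organ. In 3 of 4 such checks, on 11, 13 and 5 genes, every library lay with its cultivar. The fourth, on 14 genes higher in Guozhen in root and read in leaf, left 2 libraries out of place. Nothing was left out of the table apart from genes below the filter, and pathway lists and read-level data were not analysed here.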

Results

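Expression was read from 48 libraries of tomato seedlings of the cultivars Guizhen No.1 and Guozhen No.1, grown hydroponically at normal nitrogen (9 mM) or low nitrogen (1 mM), with roots and leaves taken at day 1 and day 7. Each of the 16 combinations of cultivar, organ, day and nitrogen level held 3 libraries. The deposited table listed 29898 genes, of which 28005 carried a tomato locus number and 1893 were newly assembled by the authors. Root tests covered 20435 genes and leaf tests 19815, and 18239 genes were tested in both organs. The comparisons between nitrogen levels, between cultivars and of the response between cultivars were fixed before the data were examined. All changes below are differences of mean log2(FPKM + 1), which understate the fold of weakly expressed genes.

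In roots, the first principal component carried 58.6% of the variance and separated day 1 from day 7, and in leaves it carried 70.1%. The second component, with 8.89% of the variance in root and 5.8% in leaf, separated low from normal nitrogen at day 7. Libraries of the same group correlated at 0.947 to 0.974 in root and at 0.912 to 0.976 in leaf, the lowest value being in Guozhen leaves at day 1 under low nitrogen. Genes preferred in leaf placed all 48 libraries with their labelled organ.

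For nitrate and ammonium transport and nitrogen assimilation, 12 preset loci were read by their locus numbers. Each class was preset with the number and was not checked against a gene map. Of these, 11 were tested in each organ, and the deposited table itself gave no gene name. Solyc09g090730, preset as ammonium transporter 1.1, rose from 38.4 ± 5.25 to 245 ± 134 FPKM (SD, n = 3 each) in Guizhen roots at day 7 of low nitrogen, a log2 change of 2.45 ± 0.38 (SE, limma adjusted p = 0.00108). In Guozhen roots it rose from 66.6 ± 11.2 to 306 ± 91.0 FPKM, a log2 change of 2.15 ± 0.38 (adjusted p = 0.000583). Solyc11g011380, a cytosolic glutamine synthetase that joins ammonium to glutamate, rose from 394 ± 27.2 to 1064 ± 357 FPKM in Guizhen roots (log2 change 1.37 ± 0.22, adjusted p = 0.0015). The same locus went from 652 ± 78.7 to 1562 ± 215 FPKM in Guozhen roots (1.26 ± 0.22, adjusted p = 0.00058). Nitrite reductase Solyc10g050890 fell from 349 ± 47.7 to 114 ± 104 FPKM in Guizhen roots (log2 change -1.96 ± 0.41, adjusted p = 0.00724). It fell from 317 ± 27.3 to 40.5 ± 16.5 FPKM in Guozhen roots (-3.01 ± 0.41, adjusted p = 6.8e-05).

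In Guozhen roots at day 7, 3 further assimilation loci were called lower. Nitrate reductase Solyc11g013810 fell from 423 ± 63.2 to 224 ± 58.1 FPKM (SD, n = 3 each; log2 change -0.93 ± 0.25 SE, limma adjusted p = 0.00933). Glutamate synthase Solyc03g083440 fell from 140.2 ± 24.9 to 41.7 ± 4.65 FPKM (-1.72 ± 0.29, adjusted p = 0.000347). Glutamate synthase Solyc03g063560 fell from 43.9 ± 8.81 to 28.0 ± 6.44 FPKM (-0.63 ± 0.19, adjusted p = 0.0171). In Guizhen roots, Solyc11g013810 stood at 331 ± 60.1 and 274 ± 7.19 FPKM under normal and low nitrogen (adjusted p = 0.601). Solyc03g083440 stood there at 136 ± 44.2 and 101 ± 45.7 FPKM (adjusted p = 0.371). The difference between the cultivars in the Solyc03g083440 response was -1.26 on the log2 scale and was not called (adjusted p = 0.133). Nitrate transporter Solyc11g069750 fell in Guizhen roots from 10.4 ± 0.915 to 4.59 ± 1.09 FPKM (-1.04 ± 0.25, adjusted p = 0.0165) and was listed at 0 in leaves. Solyc04g014510, a second cytosolic glutamine synthetase, read 512 ± 24.2 and 201 ± 19.6 FPKM under normal and low nitrogen in Guozhen roots. Its adjusted p was 0.0545 over all genes and 0.0243 when adjusted over the list alone.

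As a list, the 11 loci moved in both directions in roots at day 7. In Guizhen, 2 were called higher, 2 lower and 7 not, against 4 called when adjusted over the list alone. In Guozhen, 2 were called higher, 4 lower and 5 not, against 7 called when adjusted over the list alone. Camera gave no direction (limma, adjusted over the 8 responses, adjusted p = 0.905 in Guizhen and 0.435 in Guozhen), with list medians of 0.05 and -0.38 on the log2 scale. Some of these calls were lost when 1 library was left out, for several of them whichever of 2 or more libraries it was. Without Guizhen low nitrogen replicate 1 or 2, Solyc10g050890 in Guizhen had an adjusted p of 0.0557 or 0.0604. Solyc11g069750 had 0.108 or 0.0506, and 0.0552 without normal nitrogen replicate 2. Without Guozhen low nitrogen replicate 1, Solyc11g013810 had 0.0514. Solyc03g063560 had 0.0684 and 0.0719 without Guozhen normal nitrogen replicates 1 and 2, and 0.0917 and 0.0525 without low nitrogen replicates 1 and 2. Fitted on the 6 Guizhen libraries alone, none of the 4 Guizhen root loci stayed called, and on the 6 Guozhen libraries Solyc03g063560 was lost and Solyc04g014510 was called lower (log2 change -1.35, adjusted p = 0.00358). A pseudocount of 0.1 ended the call of Solyc11g069750.

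**Figure D1:**
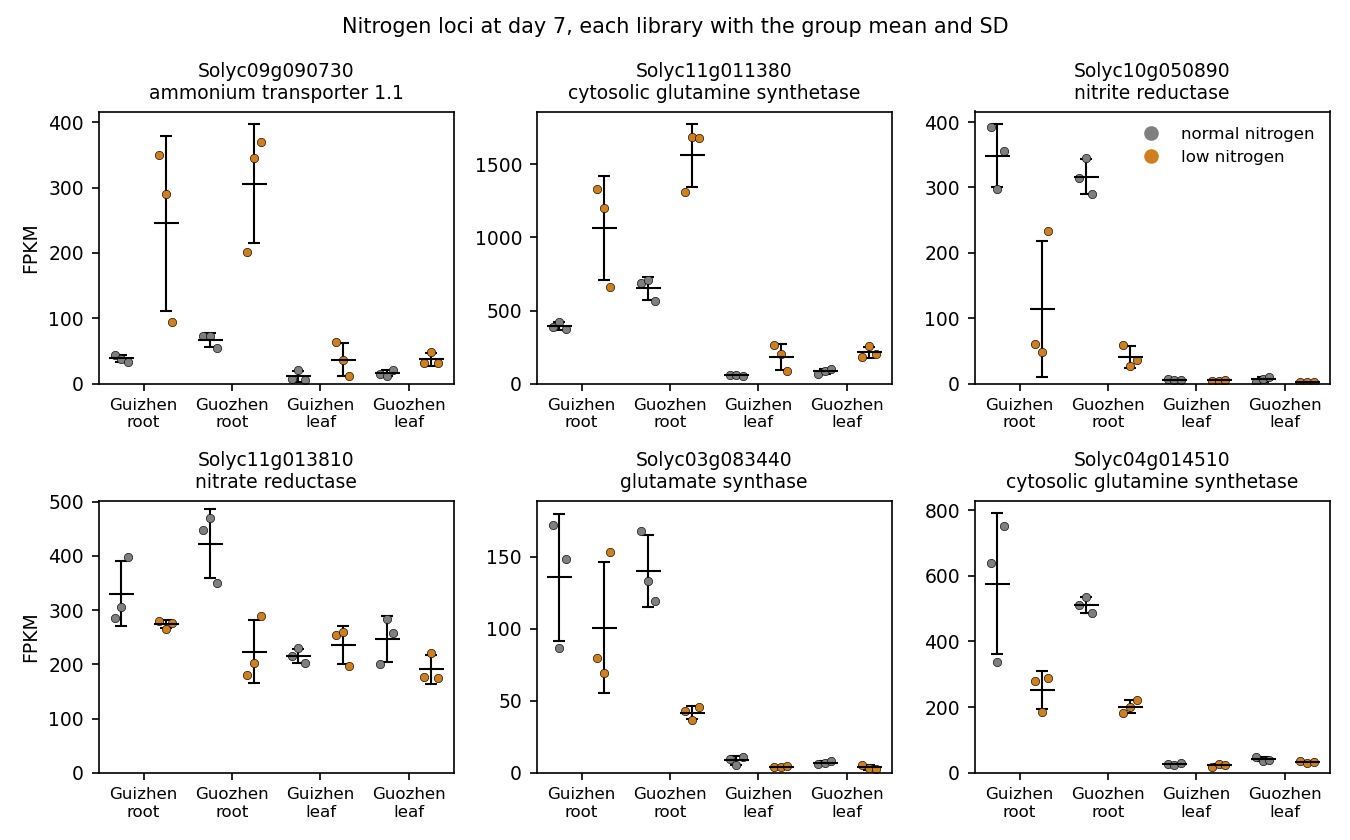
FPKM of 6 preset nitrogen loci at day 7 in each library, by cultivar and organ, with the group mean and SD (n = 3; grey, normal nitrogen; orange, low nitrogen). Solyc09g090730 and Solyc11g011380 were higher and Solyc10g050890 lower under low nitrogen in roots of both cultivars, with means of 245 against 38.4, 1064 against 394 and 114 against 349 FPKM in Guizhen.

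Across all root genes at day 7, the largest rise in Guizhen was that of Solyc06g074990, from 2.21 ± 0.530 to 329 ± 37.3 FPKM (SD, n = 3 each; log2 change 6.69 ± 0.50 SE, limma adjusted p = 3.24e-07). Solyc08g065670 followed, from 1.73 ± 0.490 to 110.3 ± 33.7 FPKM in Guizhen (5.32 ± 0.38, adjusted p = 1.83e-07). In Guozhen it rose from 3.06 ± 1.69 to 137 ± 18.4 FPKM (5.16 ± 0.38, adjusted p = 5.98e-07). Solyc07g053370 fell from 84.1 ± 41.4 to 3.10 ± 4.87 FPKM in Guizhen (-4.96 ± 0.57, adjusted p = 7.93e-05). The Guozhen fall was from 53.4 ± 8.36 to 0.632 ± 0.642 FPKM (-5.13 ± 0.57, adjusted p = 1.32e-05). Solyc03g119180 fell in Guizhen from 63.6 ± 15.4 to 11.7 ± 19.5 FPKM (-3.91 ± 0.79, adjusted p = 0.00577). In Guozhen, Solyc08g007430 fell from 374 ± 88.2 to 7.96 ± 9.48 FPKM (-6.14 ± 1.40, adjusted p = 0.00358). Solyc11g005670 rose there from 0.390 ± 0.461 to 65.4 ± 12.7 FPKM (5.61 ± 1.82, adjusted p = 0.0279), but without any 1 of the 6 Guozhen libraries its adjusted p lay between 0.0524 and 0.074.

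Low nitrogen at day 7 raised 905 and lowered 713 genes in Guizhen roots (7.92% of those tested; limma, Benjamini-Hochberg), and raised 2622 and lowered 3018 genes in Guozhen roots (27.6%). At least 2-fold changes were seen in 339 and 268 of the Guizhen genes and in 808 and 517 of the Guozhen genes. The excess of lowered genes in Guozhen did not hold: after median-of-ratios scaling 3142 were higher and 2566 lower (55.0% of calls higher against 46.5%), and with only the 6 libraries 1886 were higher and 1711 lower. The Guizhen count depended on single libraries. It was 658 without normal nitrogen replicate 2 and 858 without normal nitrogen replicate 3. It was 503 without low nitrogen replicate 1, 457 without low nitrogen replicate 2 and 2977 without low nitrogen replicate 3. Fitted on the 6 libraries alone, 18 genes were called in Guizhen and 3597 in Guozhen. In Guizhen, Solyc06g074990 and Solyc08g065670 were among them and Solyc07g053370 and Solyc03g119180 were lost.

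**Figure D2:**
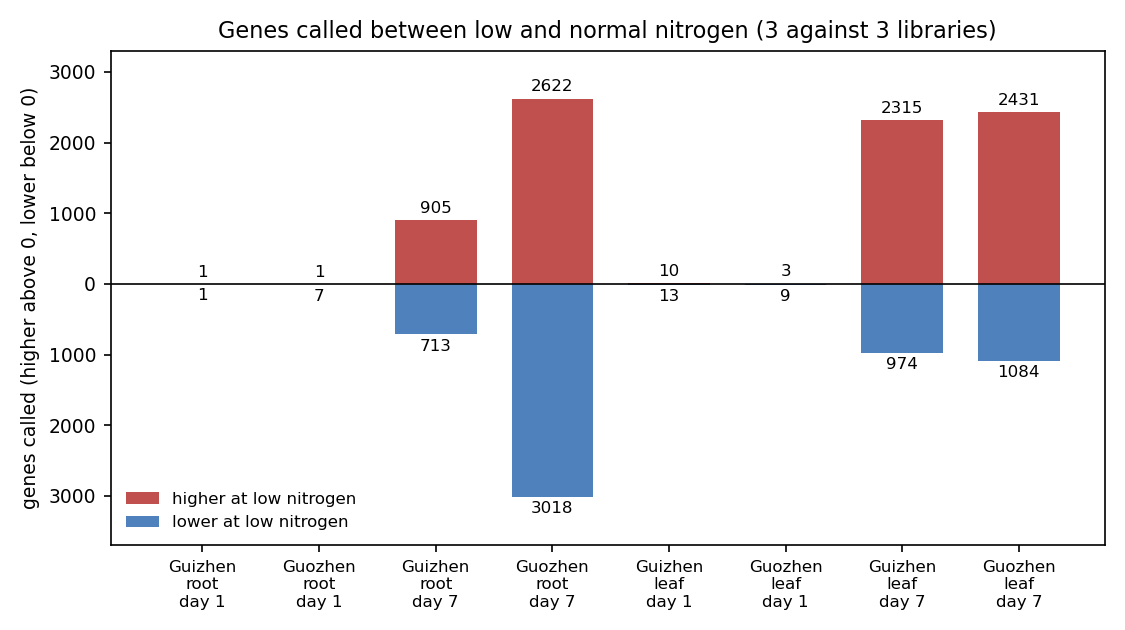
Genes called higher (red, above 0) or lower (blue, below 0) under low than under normal nitrogen, for each cultivar, organ and day (3 against 3 libraries; limma, adjusted p below 0.05). Day 7 roots gave 905 and 713 calls in Guizhen and 2622 and 3018 in Guozhen, and day 7 leaves gave 2315 and 974 in Guizhen and 2431 and 1084 in Guozhen.

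In leaves at day 7, Solyc11g011380 rose from 54.9 ± 2.69 to 184 ± 89.2 FPKM in Guizhen (SD, n = 3 each; log2 change 1.58 ± 0.30 SE, limma adjusted p = 0.00608). In Guozhen leaves it rose from 83.6 ± 15.8 to 213 ± 38.7 FPKM (1.34 ± 0.30, adjusted p = 0.00613). Ammonium transporter Solyc09g090730 rose in Guizhen leaves from 10.8 ± 8.21 to 36.7 ± 25.6 FPKM (1.60 ± 0.45, adjusted p = 0.0237). In Guozhen leaves it read 15.6 ± 4.29 and 37.1 ± 10.04 FPKM under normal and low nitrogen, with an adjusted p of 0.0718 over all genes and 0.0425 over the list alone. Glutamate synthase Solyc03g083440 fell from 8.65 ± 3.03 to 4.21 ± 0.667 FPKM in Guizhen (-0.84 ± 0.25, adjusted p = 0.0315). Its Guozhen fall was from 7.08 ± 1.14 to 3.81 ± 1.56 FPKM (-0.79 ± 0.25, adjusted p = 0.0372). Solyc04g050440, preset as ammonium transporter 1.2, fell in Guizhen leaves from 13.8 ± 6.24 to 5.05 ± 2.61 FPKM (-1.30 ± 0.39, adjusted p = 0.0307). Solyc10g050890 fell in Guozhen leaves from 6.34 ± 3.73 to 2.42 ± 0.236 FPKM (-0.96 ± 0.29, adjusted p = 0.0262). Plastid glutamine synthetase Solyc01g080280, the most abundant of the loci in leaf, read 1517 ± 76.6 and 1054 ± 152 FPKM in Guizhen (adjusted p = 0.249) and 1470.3 ± 121 and 1157 ± 249.9 FPKM in Guozhen (adjusted p = 0.469).

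Of the 11 loci tested in leaves at day 7, 2 were called higher and 2 lower in Guizhen, and 1 higher and 2 lower in Guozhen, with 4 called in each cultivar when adjusted over the list alone. Camera placed the list lower in Guozhen (p = 0.0298), but with the correlation between the loci estimated from the data p was 0.16. Adjusted over the 8 responses p was 0.119, and after median-of-ratios scaling the unadjusted p was 0.0682. In Guizhen p was 0.139. With that scaling, glutamate synthase Solyc03g063560 was called lower in Guozhen leaves (log2 change -0.73, adjusted p = 0.0411, against -0.58 and 0.0932 without it). Only the Solyc11g011380 calls among these leaf loci stood whichever library was left out. Leaving out Guizhen normal nitrogen replicate 1, 3, low nitrogen replicate 1 or 2 gave Solyc09g090730 an adjusted p of 0.0826, 0.105, 0.138 or 0.0934. For Guizhen Solyc03g083440 the values were 0.107, 0.129, 0.108 or 0.107. Solyc04g050440 had 0.0534, 0.132, 0.144 and 0.0998 without Guizhen normal nitrogen replicates 1 and 2 and low nitrogen replicates 1 and 2. In Guozhen, leaving out normal nitrogen replicate 2, 3, low nitrogen replicate 2 or 3 gave Solyc03g083440 an adjusted p of 0.09, 0.114, 0.124 or 0.168. Solyc10g050890 had 0.0891, 0.14, 0.086 or 0.0572, and 0.0543 without low nitrogen replicate 1. With only the 6 libraries of a comparison in the fit, none of the leaf loci was called, and with no filter on low values Guozhen Solyc03g083440 was lost.

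Among all leaf genes at day 7, Solyc01g108710 fell from 45.2 ± 12.5 to 5.34 ± 8.43 FPKM in Guizhen (SD, n = 3 each; log2 change -3.79 ± 0.74 SE, limma adjusted p = 0.00677). Its Guozhen values were 19.3 ± 11.4 and 0.333 ± 0.486 FPKM (-3.76 ± 0.74, adjusted p = 0.00335). Solyc07g065900 fell in Guizhen from 255 ± 27.8 to 11.7 ± 18.6 FPKM (-5.75 ± 1.16, adjusted p = 0.00742). Solyc07g053020 rose there from 6.08 ± 10.4 to 27.4 ± 2.64 FPKM (3.33 ± 0.91, adjusted p = 0.0216), and Solyc07g008210 from 0.0622 ± 0.0353 to 16.3 ± 17.5 FPKM (2.998 ± 0.90, adjusted p = 0.0304). In Guozhen, Solyc03g096160 rose from 0.548 ± 0.947 to 10.5 ± 5.94 FPKM (2.86 ± 0.48, adjusted p = 0.00135) and Solyc01g007670 from 88.0 ± 76.1 to 271 ± 65.6 FPKM (3.27 ± 1.06, adjusted p = 0.0384). Solyc10g083140 fell in Guozhen from 25.9 ± 8.31 to 0.135 ± 0.00893 FPKM (-4.51 ± 0.76, adjusted p = 0.0014). Solyc07g053020 lost its call without Guizhen normal nitrogen replicate 1 or 3 or low nitrogen replicate 1 or 2 (adjusted p 0.0745 to 0.0955). Solyc07g008210 lost its call without any normal nitrogen library or low nitrogen replicate 1 or 2 (0.0681 to 0.171). Solyc01g007670 had an adjusted p of 0.116 and 0.105 without Guozhen low nitrogen replicates 2 and 3 and of 0.0512 after scaling. It also lost its call with a pseudocount of 0.1 and with no filter on low values. Its log2 change of 3.27 was larger than its group means give, as its normal nitrogen libraries spread widely (SD 76.1 at a mean of 88.0). A very low value among them would have that effect, and whether it was a failed estimate was not tested.

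At day 7, 2315 genes were higher and 974 lower under low nitrogen in Guizhen leaves (16.6% of those tested; limma, Benjamini-Hochberg), and 2431 were higher and 1084 lower in Guozhen leaves (17.7%). Of these, 261 and 305 changed at least 2-fold in Guizhen and 305 and 299 in Guozhen. The excess of genes called higher came with a shift of the whole distribution: the median change of all genes was 0.16 in Guizhen and 0.14 in Guozhen, and median-of-ratios scaling moved it by -0.13 and -0.12. After that scaling, 999 genes were higher and 1590 lower in Guizhen (38.6% of calls higher against 70.4%), and 1309 higher and 1739 lower in Guozhen (42.9% against 69.2%). The Guizhen count was 1497, 1780 and 1483 without normal nitrogen replicates 1, 2 and 3, and 793 and 619 without low nitrogen replicates 1 and 2. The Guozhen count was 1785 without normal nitrogen replicate 2 and 1180 and 1915 without low nitrogen replicates 2 and 3. Fitted on the 6 libraries alone, 2 genes were called in Guizhen and 25 in Guozhen, and of the genes named above only Solyc10g083140 was among them.

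The cultivars shared much of the day 7 response. In roots, 593 genes were called higher in both cultivars, against 116.1 expected for independent lists (hypergeometric test, log10 p = -319.683), and 481 lower in both, against 105.3 (log10 p = -234.547). In leaves, 1068 were called higher in both, against 284 expected (log10 p = -431.864), and 565 lower in both, against 53.3 (log10 p = -507.424). These p-values treat genes as independent draws and do not measure the spread between samples. Both lists also take each gene's spread from the same fit, which favours calls of the same genes. Called genes moved in opposite directions in 4 of 1078 shared root genes and in 3 of 1636 shared leaf genes. Among genes called in either cultivar, 82.1% of 6180 in root and 95.2% of 5168 in leaf changed in the same direction. The changes of all tested genes correlated between the cultivars at 0.55 in root and 0.61 in leaf. With an adjusted p below 0.01 in place of 0.05, 336 root genes and 251 leaf genes were shared. The overlaps were not repeated with median-of-ratios scaling. That scaling took the leaf genes called higher from 2315 to 999 in Guizhen and from 2431 to 1309 in Guozhen. A shift of all genes common to both cultivars can add to the leaf genes called higher in both and to the same-direction share. One of the opposite leaf genes, Solyc10g083140.1, was singled out after its values were seen: it fell in Guozhen and rose in Guizhen by 2.29 on the log2 scale (adjusted p = 0.0453), and the difference of -6.81 between the cultivars was not called (adjusted p = 0.0797).

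**Figure D3:**
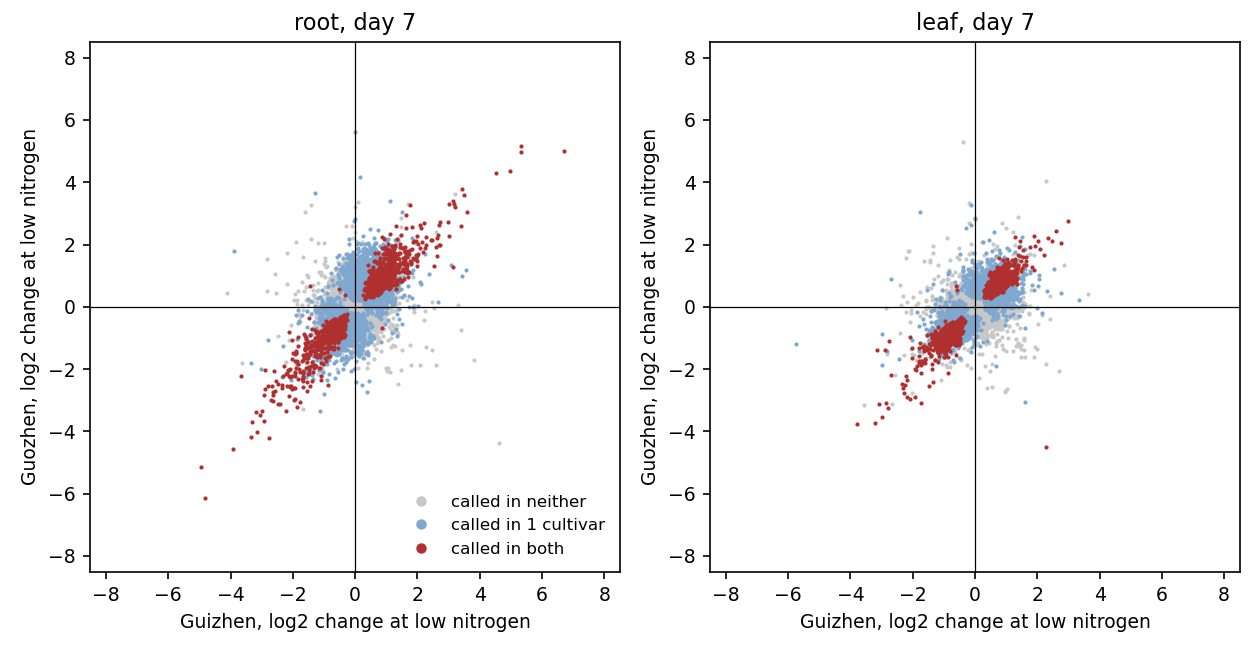
Log2 change under low nitrogen at day 7 in Guozhen against Guizhen, 1 point per tested gene, in root and leaf (red, called in both cultivars; blue, called in 1). Correlations were 0.55 in root and 0.61 in leaf, and 4 and 3 genes called in both lay in opposite directions.

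Low nitrogen at day 1 changed few genes in roots. In Guizhen roots 2 genes were called. Solyc09g064940 fell from 119 ± 32.8 to 0.237 ± 0.0563 FPKM (SD, n = 3 each; log2 change -6.57, limma adjusted p = 4.59e-16). Solyc09g064930, the neighbouring locus number, rose from 31.7 ± 3.92 to 53.1 ± 6.90 FPKM (0.73, adjusted p = 0.0112). In Guozhen roots 1 gene was called higher and 7 lower. Among the lower, Solyc09g082760 fell from 8.12 ± 1.44 to 1.59 ± 0.941 FPKM (-1.87, adjusted p = 0.0411), and Solyc12g008600 fell from 11.5 ± 2.99 to 3.38 ± 0.206 FPKM (-1.48, adjusted p = 0.0411). None of the 11 preset loci was called at day 1 in either root, over all genes or over the list alone (unadjusted p below 0.05 in 2 in Guizhen and 0 in Guozhen). Camera placed the list lower in Guizhen roots (p = 0.0294), but p was 0.268 with the correlation between the loci estimated from the data. Unadjusted p below 0.05 was reached by 1815 genes in Guizhen and 876 in Guozhen, against 1022 by chance.

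The root counts at day 1 moved with single libraries. In Guizhen 8 and 57 genes were called without normal nitrogen replicates 2 and 3, and 22 and 7 without low nitrogen replicates 1 and 2. In Guozhen the count fell to 2, 4 and 1 without normal nitrogen replicates 1, 2 and 3 and to 2 without low nitrogen replicate 1. Solyc09g082760 lost its call without any 1 of the normal nitrogen libraries or low nitrogen replicate 1 or 3 (adjusted p 0.0784 to 0.298). Solyc12g008600 lost its call without normal nitrogen replicate 1 or 3 or any 1 of the low nitrogen libraries (0.124 to 0.298). With no filter on low values 20 genes were called in Guizhen, with scaling 4 and with only the 6 libraries 6, when Solyc09g064930 was lost. In Guozhen, no gene was called with a pseudocount of 0.1 and 2 were called with only the 6 libraries, neither of them Solyc09g082760 or Solyc12g008600. As well, Solyc12g008600 was also lost with no filter.

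In Guizhen leaves at day 1, 10 genes were called higher and 13 lower (limma, Benjamini-Hochberg; 2700 genes with unadjusted p below 0.05 against 991 by chance). Solyc01g007020 fell from 10.1 ± 1.01 to 2.56 ± 0.114 FPKM (SD, n = 3 each; log2 change -1.64 ± 0.23 SE, adjusted p = 0.00459) and kept its call under every alternative run. Solyc03g006210 rose from 3.88 ± 1.48 to 11.9 ± 3.17 FPKM (1.42, adjusted p = 0.0377) and Solyc09g018460 from 3.24 ± 0.810 to 12.2 ± 4.98 FPKM (1.57, adjusted p = 0.0477). Solyc05g005310 fell from 6.66 ± 1.42 to 0.724 ± 1.05 FPKM (-2.30, adjusted p = 0.0477). No preset locus was called over all genes (4 had an unadjusted p below 0.05), and nitrite reductase Solyc01g108630, at 51.3 ± 25.6 and 22.3 ± 6.42 FPKM, reached an adjusted p of 0.138 over all genes and 0.0266 over the list alone. Left out singly, normal nitrogen replicates 2 and 3 gave 111 and 9 calls and low nitrogen replicates 1, 2 and 3 gave 149, 5 and 7. Solyc03g006210 lost its call without normal nitrogen replicate 1 or low nitrogen replicate 2 or 3 (adjusted p 0.114 to 0.217). Solyc09g018460 lost its call without normal nitrogen replicate 1 or 3 or low nitrogen replicate 2 or 3 (0.113 to 0.244). Solyc05g005310 did so without normal nitrogen replicate 1 or 3 or low nitrogen replicate 1 or 3 (0.0557 to 0.221) and after scaling (0.064). With a pseudocount of 0.1 there were 6 calls, with no filter 66 and with only the 6 libraries 5. These 3 genes lost their calls with that pseudocount and with only the 6 libraries.

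In Guozhen leaves at day 1, 3 genes were called higher and 9 lower (limma; 2034 genes with unadjusted p below 0.05). Solyc01g089890 rose from 0.783 ± 0.328 to 13.7 ± 2.32 FPKM (SD, n = 3 each; log2 change 3.04 ± 0.37 SE, adjusted p = 0.000931) and Solyc09g015170 from 2.76 ± 0.483 to 21.2 ± 2.64 FPKM (2.56 ± 0.35, adjusted p = 0.00446). Solyc12g008600 fell from 7.15 ± 1.56 to 1.13 ± 0.350 FPKM (-1.93 ± 0.19, adjusted p = 6.02e-05) and Solyc09g092520 from 86.8 ± 20.5 to 21.7 ± 7.21 FPKM (-1.97 ± 0.33, adjusted p = 0.0245). Leaving out low nitrogen replicate 3 raised the count to 1969 genes, 1027 higher and 942 lower, with all 12 genes among them. Plastid glutamine synthetase Solyc01g080280 (log2 change -1.15, adjusted p = 0.00967), cytosolic glutamine synthetase Solyc04g014510 (-1.002, adjusted p = 0.0337), glutamate synthase Solyc03g063560 (-0.87, adjusted p = 0.0102) and ammonium transporter Solyc03g045070 (-1.39, adjusted p = 0.00256) were then called lower. With all libraries none of the 11 loci was called, over all genes or over the list alone, and 2 had an unadjusted p below 0.05. The count was 7 and 6 without normal nitrogen replicates 1 and 3, 8 and 7 without low nitrogen replicates 1 and 2, 24 with no filter on low values and 7 with only the 6 libraries. Solyc09g092520 had an adjusted p of 0.0763, 0.145 and 0.17 without normal nitrogen replicates 1 and 3 and low nitrogen replicate 2. With only the 6 libraries it was lost, as was Solyc12g008600, and with a pseudocount of 0.1 Solyc01g089890 had 0.0531.

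At day 1, 3 genes were called lower in root and in leaf of Guozhen, and were singled out after their values were seen. Solyc12g008600.1 fell by 1.48 in root and 1.93 in leaf on the log2 scale, Solyc01g106690.2 by 0.89 and 1.53, and Solyc08g077210.2 by 0.88 and 1.13. Their overlap, from lists of 7 and 9 genes, had a log10 p of -8.54 in a hypergeometric test chosen after the data were seen. At day 7 the same test gave 223 genes higher in root and leaf of Guizhen, against 94.1 expected, and 97 lower, against 31.2. Of 354 genes called in both Guizhen organs, 34 went in opposite directions. In Guozhen 517 were higher in both organs, against 265.9 expected, 371 lower, against 167.2, and 213 of 1101 shared genes went in opposite directions. The expected numbers hold for independent lists, and the labels do not say whether root and leaf were taken from the same plants. Day 1 and day 7 changes of all genes correlated within a cultivar and organ at 0.12 in Guizhen root, -0.01 in Guozhen root, 0.09 in Guizhen leaf and -0.00 in Guozhen leaf. Between the cultivars, day 1 changes correlated at -0.09 in root and 0.43 in leaf.

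The response differed between the cultivars in 15 root genes at day 1 (interaction test in limma, 6 higher and 9 lower in Guozhen than in Guizhen). Solyc09g064940, at 88.1 to 153 FPKM in the 3 Guizhen roots at normal nitrogen, differed by 6.51 on the log2 scale (adjusted p = 3.41e-13) and was the 1 named gene to keep its call whichever library was left out. Solyc05g005680 went from 49.1 ± 29.4 to 9.24 ± 1.13 FPKM in Guozhen and from 9.89 ± 3.98 to 24.2 ± 11.3 FPKM in Guizhen (SD, n = 3 each; difference -3.33, adjusted p = 0.0319). Solyc05g005680 lost its call (adjusted p 0.0567 to 0.131) without any 1 of Guizhen normal nitrogen replicates 1 and 2, Guizhen low nitrogen replicates 2 and 3, Guozhen normal nitrogen replicates 1 and 3 and Guozhen low nitrogen replicates 1 and 2. The count was 1 without Guizhen normal nitrogen replicate 1 or 2, Guizhen low nitrogen replicate 3, Guozhen normal nitrogen replicate 3 or Guozhen low nitrogen replicate 2. There were 2 calls without Guizhen low nitrogen replicate 2 or Guozhen normal nitrogen replicate 1. It was 3, 10 and 24 without Guozhen low nitrogen replicate 1, Guozhen normal nitrogen replicate 2 and Guozhen low nitrogen replicate 3, and 84 without Guizhen normal nitrogen replicate 3. It was 4 with a pseudocount of 0.1 or with only the 12 libraries compared, when Solyc05g005680 was lost.

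At day 7 the root response differed between the cultivars in 79 genes (interaction test in limma, 36 higher and 43 lower in Guozhen; 3517 with unadjusted p below 0.05). Solyc12g098770 went from 68.5 ± 5.40 to 208 ± 22.1 FPKM in Guozhen roots and from 119 ± 26.0 to 81.1 ± 25.04 FPKM in Guizhen roots (SD, n = 3 each; difference 2.16 ± 0.42 SE, adjusted p = 0.0362). Solyc12g094620 went from 356 ± 28.3 to 84.6 ± 28.1 FPKM in Guozhen and from 405 ± 83.7 to 281 ± 72.6 FPKM in Guizhen (-1.57 ± 0.31, adjusted p = 0.0362). None of the 11 preset loci was called for this difference at day 1 or day 7, over all genes or over the list alone, with an unadjusted p below 0.05 in 0 and 3 of them. Both named genes lost their calls without Guizhen normal nitrogen replicate 2 or 3, Guizhen low nitrogen replicate 1, any 1 of the Guozhen normal nitrogen libraries or Guozhen low nitrogen replicate 1. Solyc12g098770 lost its call also without Guozhen low nitrogen replicate 2 (adjusted p 0.0512 to 0.117, against 0.0611 to 0.116 for Solyc12g094620). The count was 9 and 39 without Guizhen normal nitrogen replicates 2 and 3, and 17 and 124 without Guizhen low nitrogen replicates 1 and 3. It was 50, 13 and 10 without the 3 Guozhen normal nitrogen libraries in order, and 13, 50 and 326 without the 3 Guozhen low nitrogen libraries in order. It was 21 with a pseudocount of 0.1, when both named genes were lost, 173 with no filter and 0 with only the 12 libraries compared. After scaling 43 genes were higher and 14 lower (75.4% higher against 45.6%).

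Guizhen low nitrogen replicate 3 of day 7 stood between the nitrogen levels in both organs. On a score that ran from 0 at the Guizhen normal nitrogen mean to 1 for a full Guozhen response, a measure chosen after the data were seen, the Guizhen low nitrogen roots scored 0.582, 0.691 and 0.313 and the leaves 0.763, 0.872 and 0.4001. On the matching score along the Guizhen response, Guozhen low nitrogen leaves scored 0.422, 1.02 and 0.761, so that replicate 1 there lay about as low, and Guozhen low nitrogen roots scored 0.717, 0.919 and 0.945.

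**Figure D4:**
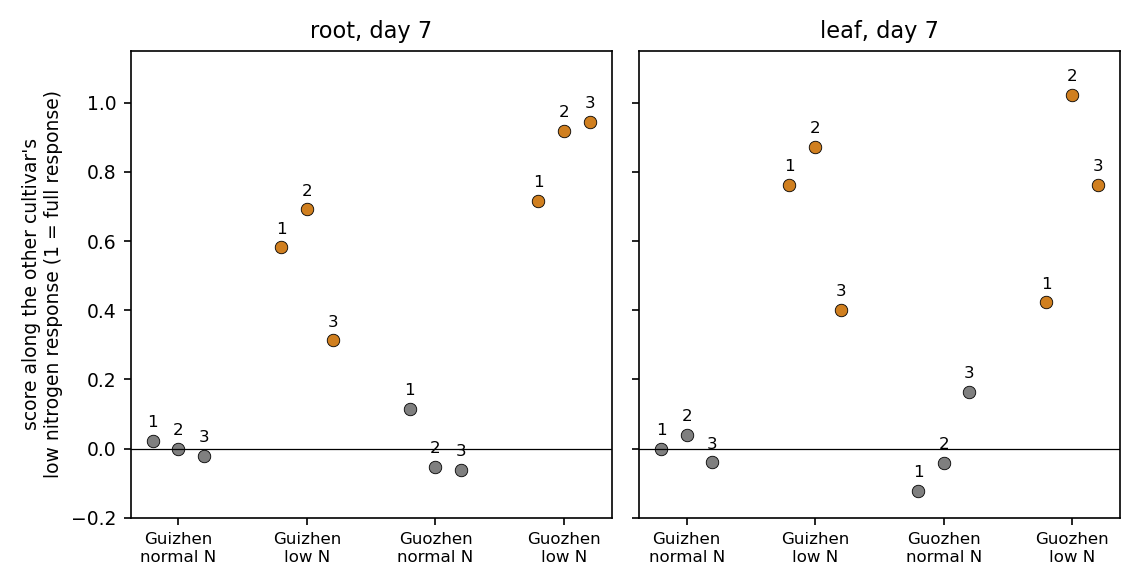
Score of each day 7 library along the other cultivar's low nitrogen response, where 1 is a full response (grey, normal nitrogen; orange, low nitrogen; numbers are replicates). Guizhen low nitrogen replicate 3 scored 0.313 in root and 0.4001 in leaf, and Guozhen low nitrogen replicate 1 scored 0.422 in leaf.

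In leaves at day 1 the response differed between the cultivars in 17 genes (interaction test in limma, 3 higher and 14 lower in Guozhen). Solyc01g089890, raised in Guozhen, read 22.8 ± 5.89 and 15.1 ± 6.25 FPKM under normal and low nitrogen in Guizhen (SD, n = 3 each; difference 3.65, adjusted p = 0.0106). Solyc03g098710 went from 21.1 ± 18.5 to 2.66 ± 3.10 FPKM in Guozhen and from 0.889 ± 0.990 to 9.49 ± 3.24 FPKM in Guizhen (difference -5.09, adjusted p = 0.0152). Without Guizhen low nitrogen replicate 2 their adjusted p was 0.0607 and 0.0659, and both were lost with a pseudocount of 0.1. The count was 31, 1 and 10 without Guizhen low nitrogen replicates 1, 2 and 3, 5 and 7 without Guozhen normal nitrogen replicates 1 and 3, and 3 and 26 without Guozhen low nitrogen replicates 2 and 3. It was 8 with a pseudocount of 0.1 and 2 with only the 12 libraries, when Solyc03g098710 was lost. In leaves at day 7 limma called 0 genes, with 1055 at unadjusted p below 0.05 against 991 by chance, and the count stayed at 0 to 3 under every alternative. It was 3 without Guizhen normal nitrogen replicate 1 or 2, 2 without Guizhen low nitrogen replicate 1 or Guozhen normal nitrogen replicate 1, and 1 with no filter on low values. No preset locus was called for a cultivar difference in its leaf response, over all genes or over the list alone, with an unadjusted p below 0.05 in 1 at day 1 and 0 at day 7.

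At normal nitrogen, the cultivars differed in 318 root genes at day 1 (190 higher and 128 lower in Guozhen; limma, Benjamini-Hochberg) and in 189 at day 7 (111 higher and 78 lower). Solyc07g043000 was listed at 0 in all 3 Guizhen roots of day 1 and at 639 to 898 FPKM in Guozhen (adjusted p = 0.0102). Solyc09g020190 was listed at 0 in Guizhen roots of day 7 and at 26.8 to 33.8 FPKM in Guozhen (adjusted p = 4.3e-05). A listed 0 can also be a failed estimate. Solyc09g018590 stood at 105 ± 27.1 FPKM in Guozhen against 0.0136 ± 0.0236 in Guizhen at day 1 (SD, n = 3 each; log2 difference 6.68, adjusted p = 3.78e-09). Solyc09g064940 was the reverse at day 1, with 0.363 ± 0.149 FPKM in Guozhen against 119 ± 32.8 in Guizhen (-6.43, adjusted p = 6.75e-16). Solyc02g077940 was listed at 0 in the Guozhen roots of day 1 and at 14.4 to 18.2 FPKM in Guizhen (adjusted p = 4.28e-13). At day 7 it stood at 0.00627 ± 0.0109 against 11.9 ± 1.65 FPKM (-3.67, adjusted p = 5.91e-12). At day 7, Solyc09g005520 was higher in Guozhen (22.5 ± 2.61 against 0.276 ± 0.460 FPKM; 4.25, adjusted p = 7.7e-06) and Solyc10g085040 lower (0.0628 ± 0.0448 against 14.8 ± 2.10 FPKM; -3.88, adjusted p = 4.9e-08). The day 1 count was 169 without Guizhen replicate 1 and 173 and 190 without Guozhen replicates 1 and 3, and with only the 6 libraries the counts were 146 and 88.

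In leaves at normal nitrogen, 379 genes were higher and 200 lower in Guozhen at day 1, and 58 were higher and 79 lower at day 7 (limma, Benjamini-Hochberg). Solyc09g005520 was again higher in Guozhen at day 7 (16.1 ± 6.65 against 0.0201 ± 0.0184 FPKM; SD, n = 3 each; log2 difference 3.998, adjusted p = 1.85e-09) and Solyc10g085040 again lower (0.866 ± 0.826 against 38.8 ± 2.76 FPKM; -4.51, adjusted p = 6.02e-08). Solyc00g026160 was lower in Guozhen at day 1 (41.1 ± 39.1 against 617 ± 113 FPKM; -4.47, adjusted p = 5.26e-05), and lost its call with only the 6 libraries. Solyc08g078920 was also lower at day 1 (26.0 ± 44.8 against 143 ± 40.7 FPKM; -4.94, adjusted p = 0.0111), with adjusted p of 0.0581, 0.076 and 0.0832 without Guizhen replicate 2 and Guozhen replicates 1 and 3 and of 0.17 with only the 6 libraries. Among genes higher in Guozhen at day 1, Solyc10g011930 was listed at 0 in all 3 Guizhen leaves and at 17.0 to 33.9 FPKM in Guozhen (adjusted p = 0.0284, or 0.0519 to 0.0987 without any 1 of the 6 libraries). Solyc00g282510 stood at 25.2 ± 1.91 against 0.0905 ± 0.112 FPKM (4.59, adjusted p = 0.0229, or 0.07 to 0.0867 without any 1 library but Guizhen replicate 3). Solyc12g062200 was higher at day 7 (8.54 ± 0.905 against 0.295 ± 0.511 FPKM; 2.94, adjusted p = 0.0104), with 0.0576, 0.057 and 0.0519 without Guizhen replicates 1 and 3 and Guozhen replicate 1. Solyc01g103210 was lower at day 7 (0.0720 ± 0.0301 against 30.5 ± 4.37 FPKM; -4.87, adjusted p = 0.0208), with 0.0597 to 0.0833 without any 1 of the 6 libraries. None of the 11 preset loci was called between the cultivars in either organ at either day, over all genes or over the list alone (unadjusted p below 0.05 in 0 and 1 in root and 1 and 0 in leaf at days 1 and 7). Without Guizhen replicate 3 cytosolic glutamine synthetase Solyc04g014510 was called higher in Guozhen leaves at day 1 (log2 difference 1.40, adjusted p = 0.011, against 1.004 and 0.0928). The day 1 count was 382 and 289 without Guizhen replicates 1 and 2 and 308, 351 and 325 without the 3 Guozhen replicates in order. After scaling 276 genes were higher and 294 lower (48.4% higher against 65.5%). At day 7 the count was 82 without Guozhen replicate 3 and 67 with only the 6 libraries.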

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

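The tests of the difference of the response between days, of a label swap, of a leaf mixture and of depth for Guizhen day 7 replicate 3, of depth and stage for Guozhen leaf day 1 replicate 3, the windows of consecutive loci and the counts over splits that mixed both cultivars or both days were chosen only after the results were seen.

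The low nitrogen response differed between the cultivars by an interaction test in limma in 15 root genes at day 1, 79 root genes at day 7 and 17 leaf genes at day 1. Among named genes, the log2 differences (Guozhen minus Guizhen) were 6.51 for Solyc09g064940, 2.77 for Solyc04g078340, -3.69 for Solyc11g017440 and -3.33 for Solyc05g005680 in roots at day 1. They were 2.29 for Solyc07g009310, 2.16 for Solyc12g098770, -1.62 for Solyc06g006080 and -1.57 for Solyc12g094620 in roots at day 7, and 3.65 for Solyc01g089890, -5.09 for Solyc03g098710 and -4.69 for Solyc03g098720 in leaves at day 1. Solyc09g064940 kept its call whichever library was left out. Solyc04g078340 and Solyc11g017440 lost theirs without any 1 of the 12 libraries except Guizhen normal nitrogen replicate 3, Guizhen low nitrogen replicate 1 and Guozhen normal nitrogen replicate 2 (adjusted p 0.0678 to 0.179 and 0.0639 to 0.156), and Solyc05g005680 with Guozhen low nitrogen replicate 3 as a further exception (0.0567 to 0.131). In roots at day 7 the exceptions were Guizhen low nitrogen replicate 1 and Guozhen low nitrogen replicate 3 for Solyc07g009310 (0.0525 to 0.133), Guizhen normal nitrogen replicate 1 and low nitrogen replicate 3 and Guozhen low nitrogen replicate 3 for Solyc06g006080 (0.0566 to 0.133), these 3 and Guizhen low nitrogen replicate 2 for Solyc12g098770 (0.0512 to 0.117), and these 4 and Guozhen low nitrogen replicate 2 for Solyc12g094620 (0.0611 to 0.116). In leaves Solyc01g089890 and Solyc03g098710 lost their calls without Guizhen low nitrogen replicate 2 (0.0607 and 0.0659), and Solyc03g098720 without any 1 library except Guizhen normal nitrogen replicate 2, Guozhen normal nitrogen replicate 1 and low nitrogen replicate 1 of either cultivar (0.0536 to 0.151).

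The same genes also depended on other settings. With a pseudocount of 0.1, all named genes but Solyc09g064940 lost their calls (adjusted p 0.0525 to 0.166). With only the libraries compared, all but Solyc09g064940 and Solyc01g089890 did (0.129 to 0.787). With no filter, Solyc04g078340 and Solyc11g017440 (0.0761 each) and Solyc03g098720 (0.0707) lost theirs. Solyc03g098720 also lost its call with scaling (0.0508) and with robust variance (0.054).

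Of 100 splits that regrouped libraries by nitrogen level within each cultivar, the real one included, 3 gave as many calls as the 15 in root at day 1 (highest other 34) and 3 as many as the 17 in leaf at day 1 (highest other 867). Taken for each comparison alone, these shares lie below 0.05, but several such comparisons were made, so that chance is not excluded. The highest of these splits mixed both cultivars, and what the one with 867 calls followed was not tested. Leaving out single libraries took the counts to between 1 and 84 and between 1 and 31. For the 79 in root at day 7, 10 of 100 gave as many (highest other 4066), so that chance is not excluded by that count. The highest kept all Guozhen labels and so carried the Guozhen response. Among the 84 splits that mixed both cultivars 0 gave as many (highest 64). Those splits also broke up the day 7 response of both cultivars, so that they cannot stand for equal responses and do not speak to chance. For the 0 in leaf at day 7 all 100 gave as many (highest other 2886, with all Guizhen labels kept).

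The response also differed between day 7 and day 1. In Guizhen roots 191 genes were called (122 higher, 69 lower at day 7), with ammonium transporter Solyc09g090730 at 2.39 on the log2 scale (limma adjusted p = 0.0407, or 0.0548 to 0.131 without any 1 of the 12 libraries except day 1 normal nitrogen replicate 3, day 1 low nitrogen replicate 1 and day 7 low nitrogen replicate 3). That call also ended with no filter (0.0647) and with only the libraries compared (0.165). In Guozhen roots 2713 genes were called (1282 higher, 1431 lower), with Solyc09g090730 at 2.18 (adjusted p = 0.014), nitrite reductase Solyc10g050890 at -2.67 (adjusted p = 0.00667), cytosolic glutamine synthetase Solyc11g011380 at 1.29 (adjusted p = 0.0134) and glutamate synthase Solyc03g083440 at -1.61 (adjusted p = 0.015). In leaves 316 genes were called in Guizhen (262 higher, 54 lower) and 960 in Guozhen (719 higher, 241 lower), with ammonium transporter Solyc04g050440 at -2.20 in Guizhen (adjusted p = 0.04996, or 0.0732 to 0.137 without any 1 of the 12 libraries except day 1 normal nitrogen replicate 2 and day 7 low nitrogen replicate 3). The Solyc04g050440 call also ended with a pseudocount of 0.1 (0.0516), with no filter (0.0722), with scaling (0.0608) and with only the libraries compared (0.0763). After scaling the leaf splits were 69 higher and 76 lower in Guizhen and 378 higher and 604 lower in Guozhen, and the root split in Guozhen was 1604 higher and 1161 lower. Of 100 splits that regrouped libraries by nitrogen level within each day, the real one included, 3 gave as many calls in Guizhen roots (highest other 573). In Guizhen leaves 2 did (highest other 343), in Guozhen leaves 2 (highest other 2772) and in Guozhen roots 5 (highest other 3950). Each of these highest splits kept all day 7 labels and so carried the day 7 response. Such splits stand for no response at either day and not for an equal response at both, so that these shares cannot speak to chance. Among the 84 splits that mixed both days, which also broke up the day 7 response, the highest counts were 14 in Guizhen roots and 1 in Guozhen roots. They were 8 in Guizhen leaves and 5 in Guozhen leaves.

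These day difference counts moved with single libraries. In Guizhen roots the count was 66, 120 and 111 without day 1 normal nitrogen replicates 1, 2 and 3, 59 and 68 without day 1 low nitrogen replicates 2 and 3, 67 and 87 without day 7 normal nitrogen replicates 2 and 3, and 42, 44 and 1072 without the 3 day 7 low nitrogen libraries in order. In Guozhen roots it was 1430 without day 1 normal nitrogen replicate 1. In Guizhen leaves, with libraries left out in order, it was 109, 563 and 10 for day 1 normal nitrogen, 56, 15 and 5 for day 1 low nitrogen, 48, 56 and 12 for day 7 normal nitrogen and 6, 6 and 1551 for day 7 low nitrogen. In Guozhen leaves it was 505, 318 and 109 without day 1 normal nitrogen replicates 1, 2 and 3, 159 and 2307 without day 1 low nitrogen replicates 1 and 3, 555 and 239 without day 7 normal nitrogen replicates 1 and 2, and 2108, 120 and 305 without the 3 day 7 low nitrogen libraries in order. Without Guizhen day 7 low nitrogen replicate 3, the day difference in Guizhen roots was called for Solyc10g050890 (-1.64, adjusted p = 0.0206) and Solyc11g011380 (1.499, adjusted p = 0.00257).

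The Guizhen day 7 low nitrogen libraries of replicate 3 lay nearer the normal nitrogen libraries than replicates 1 and 2 did, in root and leaf, and in leaf Guozhen low nitrogen replicate 1 scored about as low (0.422 against 0.4001). A swap with a normal nitrogen library is excluded, since its root score of 0.313 lay above all 3 normal nitrogen roots (-0.021 to 0.022) and none of those scored like a low nitrogen library. Lower depth is excluded, since its relative depth of 1.02 in root and 0.936 in leaf lay above the lowest of the other 5 libraries (0.821 and 0.865). A simple mixture with normal nitrogen RNA would give the same normal nitrogen fraction from genes that fell and from genes that rose. In leaf these fractions were 0.337 and 0.826, a difference of -0.489, and in root 0.524 and 0.724, a difference of -0.1998. The genes were chosen by the mean of replicates 1 and 2, from which the fraction was also solved. That choice can move the 2 fractions apart, so that a mixture could not be decided in either organ. A weaker or later response of the plants behind these samples stays open and was not tested.

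In Guozhen leaves at day 1, low nitrogen replicate 3 stood apart from replicates 1 and 2, and without it 1969 genes were called in place of 12. Its highest correlation with a normal nitrogen library, 0.969, was about that between low nitrogen replicates 1 and 2 (0.968). It lay below the lowest among the normal nitrogen libraries (0.973), but no other leaf group had so high a lowest correlation. None of the normal nitrogen libraries stood out of place, which argues against a swap between the groups, but a single wrong label is not excluded. Its relative depth of 0.862 was the lowest of the 12 leaf libraries of that day (next 0.879), but among 2198 genes of at least 50 FPKM, which depth hardly affects, its higher correlation with replicates 1 and 2 was 0.808, below the lowest of the other 7 leaf groups (0.864), which argues against depth. A shift along the day 1 to day 7 change could not be decided: its score was 0.0972, against -0.253 to 0.0292 for the other 5 Guozhen leaf libraries of day 1. No biological explanation was tested.

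Genes that differed between the cultivars at normal nitrogen lay in runs: among 153 genes called in at least 2 of 4 comparisons (105 higher and 48 lower in Guozhen), 14 pairs had neighbouring locus numbers, against at most 6 in 1000 random placements, which excludes chance placement. As many response genes formed 10 pairs, so that a likeness of neighbours in general could not be told apart from this for pairs, but the fullest window of 50 loci held 15 cultivar genes (chromosome 6, Solyc06g008310 to Solyc06g008970) and at most 5 response genes. Chromosomes 9 and 6 held 41 and 31 of the genes (26.8% and 20.3%, against 7.30% and 8.92% of loci). Both genes were lower in the same cultivar in 64.3% of the pairs (exact 95% interval 35.1 to 87.2, which treats pairs that share a gene as independent). A poorer match of 1 cultivar to the reference all along a run does not by itself give the other pairs. Poorer matches that change cultivar from gene to gene were not tested, so that mapping to the reference stays open. Inherited segments that differ between the cultivars stay open as a hypothesis that could not be tested without sequence.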

How the results depend on the processing

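The difference of the response between days and the overlap of root with leaf, with all their alternatives, were chosen only after the results were seen. No single gene or list result past the threshold in the main or the alternative run changed direction between them, but the balance of calls did. Changes of direction among results past the threshold in neither run were not counted. With scaling the share of calls that were higher crossed the middle in Guizhen and Guozhen leaves at day 7 (70.4% to 38.6% and 69.2% to 42.9%), Guozhen roots at day 7 (46.5% to 55.0%), the cultivar difference in the root response at day 7 (45.6% to 75.4%), the cultivars in leaf at day 1 (65.5% to 48.4%) and the day difference in Guozhen roots (47.3% to 58.0%) and Guizhen and Guozhen leaves (82.9% to 47.6% and 74.9% to 38.5%). With robust variance all 20 counts of calls stayed within 1.5 times, and of the single gene results 274 stayed on their side of the threshold and 1 lost its call. The preset list was not run with robust variance. The other settings ended 19 of these single gene calls (pseudocount 0.1), 8 (no filter), 4 (scaling, which also made 2), 42 (only the libraries compared, which also made 1), 19 (the block described below) and, with 1 library left out, 184 against 2040 that stayed as they were and 20 that were made. List results that lost the threshold are given below and are not in these numbers. No read counts were given, so that depth was weighed only through the relative depth estimated from low values. For Guozhen leaf day 1 replicate 3, genes of at least 50 FPKM were used as well. Where no cause is named below, the cause was not tested.

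With a pseudocount of 0.1 the counts were 0 in Guozhen roots and 6 in Guizhen leaves at day 1, and for the cultivar difference in the response 4 in roots at day 1, 21 at day 7 and 8 in leaves at day 1. With no filter they were 20 in Guizhen roots, 66 in Guizhen leaves and 24 in Guozhen leaves at day 1, 173 and 1 for the cultivar difference in the response in roots and leaves at day 7, and 109 for the day difference in Guizhen leaves. With scaling they were 4 in Guizhen roots at day 1 and 145 for the day difference in Guizhen leaves, where scaling moved the median of all genes by -0.16. The preset list had p = 0.268 in Guizhen roots at day 1 and p = 0.16 in Guozhen leaves at day 7 with estimated correlation, and p = 0.0682 in the latter with scaling. At an adjusted p below 0.01 the cultivars shared 336 root and 251 leaf genes at day 7.

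With only the libraries compared, which leaves fewer residual degrees of freedom, the counts were 6 and 18 in Guizhen roots at day 1 and day 7, 2 and 3597 in Guozhen roots, 5 and 2 in Guizhen leaves, and 7 and 25 in Guozhen leaves. For the cultivar difference in the response they were 4 and 0 in roots and 2 in leaves at day 1, for the cultivars at normal nitrogen 146 and 88 in roots and 67 in leaves at day 7, and for the day difference 23 in Guizhen roots and 46 and 228 in Guizhen and Guozhen leaves.

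The replicate number was tried as a block, although the numbers do not pair the samples: in no set of low and normal nitrogen libraries did all 3 same-numbered pairs correlate above 0.1. Root and leaf of Guizhen at day 7 under low nitrogen did (0.308, 0.201 and 0.355, each best with its own number), a hint from the data alone. With the block the counts were 11 and 969 in Guizhen roots at day 1 and 7, 11 in Guizhen and 7 in Guozhen leaves at day 1, 2 and 6 for the cultivar difference in the response in roots at day 7 and leaves at day 1, 122 in roots at day 7 and 309 and 65 in leaves for the cultivars at normal nitrogen, and 70, 1668 and 173 for the day difference in Guizhen roots, Guozhen roots and Guizhen leaves. Calls past the threshold without the block and not with it included Solyc03g063560 in Guozhen roots (adjusted p = 0.0629) and Solyc04g050440 in Guizhen leaves (0.0571) at day 7, and in the cultivar difference in the leaf response at day 1 Solyc01g089890 (0.0578), Solyc03g098710 (0.0866) and Solyc03g098720 (0.291).

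Leaving out 1 library gave 2 to 57 and 457 to 2977 calls in Guizhen roots at day 1 and 7, 1 to 10 and 3910 to 5099 in Guozhen roots, 5 to 149 and 619 to 4219 in Guizhen leaves, and 6 to 1969 and 1180 to 4288 in Guozhen leaves. The cultivar difference in the response gave 1 to 84 and 9 to 326 in roots and 1 to 31 and 0 to 3 in leaves, the cultivars at normal nitrogen 169 to 305 and 134 to 174 in roots and 289 to 780 and 82 to 120 in leaves. The day difference gave 42 to 1072 in Guizhen roots, 1430 to 2758 in Guozhen roots, 5 to 1551 in Guizhen leaves and 109 to 2307 in Guozhen leaves.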

Other observations

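The tests of the response against the day 1 to day 7 change and of the day 1 agreement between cultivars were chosen only after the results were seen.

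In leaves at day 7, the low nitrogen response of each cultivar ran against the day 1 to day 7 change of the other cultivar at normal nitrogen, so that no library was shared between the 2 sides. Across 19815 genes the correlations were -0.348 for the Guizhen response and -0.167 for the Guozhen response. Each library was scored along the other cultivar's change, with 0 for the day 1 mean of its own cultivar at normal nitrogen and 1 for the whole change. Low nitrogen leaves of day 7 scored 0.702, 0.766 and 0.833 against 0.937, 0.896 and 0.966 at normal nitrogen in Guizhen, and 0.847, 0.720 and 0.832 against 0.939, 0.896 and 0.833 in Guozhen, where the groups overlapped. The scores and correlations were not repeated with median-of-ratios scaling. A shift of all genes, as seen in leaves at day 7, can move the scores as well. That low nitrogen leaves stood nearer to day 1 leaves is a hypothesis that these correlations go with, more clearly in Guizhen, and slower development as its cause was not tested. In roots no such relation was seen, with correlations of -0.0721 and 0.0146, so that the idea that low nitrogen roots lay further along it was not borne out.

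The day 1 leaf responses of the cultivars correlated at 0.43, but 9 of 100 pairs of splits, the real one included, gave a correlation as far from 0 (highest other 0.562), so that arbitrary groups give such agreement too. For the day 7 correlations only the real pair of splits reached its value, in root (0.552, highest other 0.537) and in leaf (0.606, highest other 0.605). Of 200 genes preferred in leaf over root at day 1 at normal nitrogen, the median change in leaf at day 7 was -0.04 in Guizhen and 0.08 in Guozhen, below the medians of all genes (0.16 and 0.14). Camera gave p = 0.0115 and 0.0802 at the preset correlation and p = 0.507 and 0.645 with the correlation estimated from the data, so that a larger fall of these genes was not shown. In leaf at day 1 the medians were -0.62 in Guizhen and -0.52 in Guozhen, and 0.18 and 0.28 for 77 tested genes preferred in root. Both lists were chosen on normal nitrogen libraries that are also the controls there, a choice that favours these directions, so that no test was drawn from day 1.

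The 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real counts and the highest of the other splits were 2 and 9 in Guizhen roots at day 1 (5 splits gave as many), 1618 and 42 at day 7, 8 and 4 in Guozhen roots at day 1, 5640 and 4 at day 7, 23 and 3 in Guizhen leaves at day 1, 3289 and 10 at day 7, 12 and 36 in Guozhen leaves at day 1 (3 splits gave as many), and 3515 and 2 at day 7. For the cultivars at normal nitrogen they were 318 and 1 in root at day 1, 189 and 5 at day 7, 579 and 1 in leaf at day 1 and 137 and 5 at day 7. What the split with 36 calls in Guozhen leaves at day 1 followed was not tested.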
